A study of Rattus norvegicus with 6 samples.

How the data were processed

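RNA sequencing was done on nucleus pulposus cells, the cells of the gelatinous core of the intervertebral disc, from male Sprague Dawley rats. Per the labels, 3 libraries came from untreated cells and 3 from cells given 10 mM lactate for 8 h. The labels put RNA from a column kit into a kit for sequencing mRNA. They do not state whether the lactate was an acid or a salt, or whether the libraries of a group came from separate cultures or animals. The p-values below therefore measure only the spread between these libraries, which may be technical.

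The authors deposited 2 tables, of 17273 genes and of the 6359 genes that they selected, each with, for each library, raw read counts per gene and FPKM, which are counts scaled by transcript length and library total. Both also hold the authors' own comparison, with log2 fold changes and p-values, and the larger one adjusted p-values, per the file headers. Counts were taken from the larger one. The aligner, the counting tool, the gene annotation and the use of strand are not given in the sources used here. The submitters' processing notes name GRCm38 and mm10, both mouse builds, while the deposited tables use rat gene names. Which genome the reads were aligned to was therefore not settled, and no coordinates are given. Of the 17273 names, 14063 (81.4%) match a symbol or synonym of the rat assembly GRCr8, used for names only. Genes with near-identical copies, overlapping genes and antisense genes are uncertain, because the counting could split or merge their reads.

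Counts were tested as deposited with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter (13747 genes kept), group as the only term and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05, and a stricter count asked also for a 2-fold change. Levels are CPM, counts brought to a common library total, scaled by TMM factors, with the SD over 3 libraries, and fold changes are log2 of lactate over control with the standard error (SE). Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and again with an estimated one, and the p-values were adjusted over the 30 lists with at least 3 tested genes. Of the 33 lists, the macrophage and endothelial markers had too few tested genes, and the red blood cell markers were not analysed here.

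The design, the alternatives, the 33 lists and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the largest rise and the 10 with the largest fall among those called, with a gene symbol, a mean CPM of at least 1 and no overlap between groups. It added up to 4 called members of each list with the smallest p, and 20 genes whatever their result. Members that went against their list's direction, and the genes of 10 lists added later, were named after their values were seen. A few genes that the rule took are not reported here. Of the called genes taken by the rule, Alpl was the only one whose groups overlapped.

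Alternatives were RLE and upper-quartile factors, library totals with no factors, other filters, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), glmTreat against a fold of 1.2, a replicate block, fry in place of camera, and each library left out in turn. Removal of a trend on transcript length, and leaving out 32 genes with 0 counts in 1 library and over 1000 in another, were chosen after seeing the data. Relative length was taken from the ratio of deposited counts to FPKM, which gave a value for 100% of the genes tested.

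The tests were tested on simulated data for the comparison of lactate against control, with 13747 genes of which 200 were changed. At a 2-fold change edgeR recovered 65% of 100 genes, and at a 4-fold change 98% of 100. It also called 13 unchanged genes among 176 calls. DESeq2 recovered 77% and 99% but called 40 unchanged genes, and limma-voom recovered 62% and 98% with 6. The 200 changes were planted only in genes above a minimum expected count. The real comparison called 9079 genes, far more than were planted. These rates therefore do not carry over to the real comparison. With the measured fold changes planted as the truth in 13576 tested genes, TMM scaling was off by a median of 0.03 log2 units, and 99.7% of 8782 calls had the right sign. The planted fold changes and library sizes were themselves those with TMM factors. This therefore cannot decide whether TMM factors or library totals are the right scaling. With 1 of 30 lists shifted, camera called that list and 0 others. Simulated genes varied independently of each other, so this does not test camera on correlated genes or on trends with length or level.

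Libraries held 30291357 to 38989574 counts. A count of 0 in 1 library allows up to 3 counts, or 0.0769 to 0.0990 CPM on library totals without TMM factors, for counting error only. With TMM factors, as used for the levels, 3 counts came to 0.141 CPM in lactate library 2. The variation between libraries of a group, as the square root of the common dispersion, was 21.5%. Counts of 2 libraries of a group differed by 16.3 to 60.3 times the sampling noise (chi-square per degree of freedom). This covers counting error only, and does not show that the libraries came from separate cultures. No spike-in RNA was used here, so an overall rise or fall in RNA per cell was not measured.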

Results

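Gene expression was measured in cultured rat nucleus pulposus cells left untreated (3 control libraries) or given 10 mM lactate for 8 h (3 lactate libraries), to find the genes that differ after lactate. Control libraries 1, 2 and 3 held 33584741, 38989574 and 34808082 counts, and lactate libraries 1, 2 and 3 held 30576461, 30291357 and 35512356. The make-up of the libraries differed more than their size. The 20 most abundant genes took 20.1% ± 0.742 (SD, n = 3) of the counts in control and 31.9% ± 2.03 in lactate libraries. Col1a1, which encodes a chain of type I collagen, took 3.89 to 4.72% in control and 8.02 to 10.1% in lactate libraries. The median count per gene was 361 ± 25.4 (SD, n = 3) in control and 136 ± 24.4 in lactate libraries.

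Lactate libraries stood apart from control libraries over the whole transcriptome. The correlation of log2 CPM across genes averaged 0.968 within groups (0.958 to 0.974) and 0.863 between groups (0.852 to 0.875), and the first principal component, which separated the groups, held 74.6% of the variance. With edgeR, 9079 of 13747 genes were called, 4319 higher and 4760 lower, and 5588 of them changed at least 2-fold (2493 higher, 3095 lower). In 9923 genes (72.2%) the groups did not overlap, where chance gives 10%. The balance of directions depended on the scaling. The median log2 fold change was −0.10 with TMM factors and −0.96 with library totals alone, which called 1722 genes higher and 8492 lower. The share of calls that were higher was 47.6% with TMM and 16.9% with totals, and 18.0% with limma-trend on FPKM. Directions below are those with TMM, relative to the bulk of genes, and the counts and medians of the lists are also given with library totals.

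Fold changes also followed transcript length. In the shortest 1375 genes the median log2 fold change was 0.78, with 52% of genes higher and 12.7% lower, and in the longest 1375 it was −0.60, with 20% higher and 52.1% lower. Values with this trend removed, a setting chosen after seeing the data, are given for some of the lists and genes that it moved. Fold changes followed the level as well, a trend examined after seeing the data. In the 2750 genes with the lowest mean log2 CPM the median log2 fold change was −0.64, with 14.3% higher and 33.3% lower, and in the 2750 with the highest it was 0.55, with 59.2% higher and 19.8% lower. The list values below are not corrected for this. Of the TCA cycle genes 15 of 20, and of the glycolysis genes 13 of 15, were among those 2750 most abundant genes. The medians of these lists, 0.53 and 0.58, were near the 0.55 of the 2750.

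**Figure D1:**
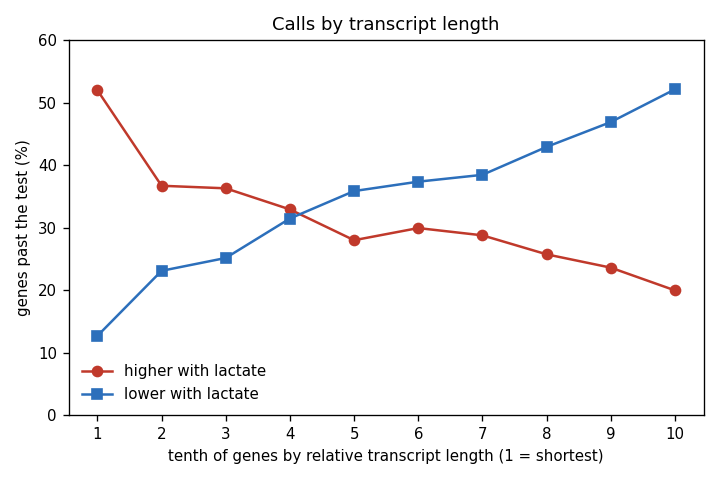
Share of genes called higher (red circles) or lower (blue squares) with lactate by edgeR, in percent, for 10 groups of genes ranked by relative transcript length (1 is the shortest). The share called higher goes from 52% in the shortest group to 20% in the longest, and the share called lower from 12.7% to 52.1%.

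Genes of the unfolded protein response, by which cells answer misfolded protein in the endoplasmic reticulum, rose. Of 20 tested, 16 were higher, 2 lower and 2 not called, the same adjusted over the list alone, with a median log2 fold change of 1.76 (0.89, with 13 higher and 4 lower, with library totals; camera adjusted p = 5.2e-05, and adjusted p = 0.45 with an estimated correlation). Hspa5, the main chaperone of the endoplasmic reticulum, went from 1457 ± 4.69 to 25304 ± 847 CPM (SD, n = 3), a log2 fold change of 4.12 ± 0.10 (SE; edgeR adjusted p = 2.3e-07). Ddit3, the stress transcription factor CHOP, rose by 4.69 ± 0.15, and Calr, the calcium-binding chaperone calreticulin, by 2.17 ± 0.09. Xbp1, a transcription factor of this response, fell by 2.18 ± 0.10, and Sel1l, of the degradation of misfolded proteins, fell by 0.96 (−0.39 with the length trend removed). Cytosolic and mitochondrial heat shock genes rose as well, 13 of 14 with 0 lower, both over all genes and adjusted over the list alone (median 1.47, and 0.62 with 11 higher and 1 lower with library totals; camera adjusted p = 5.2e-05, and adjusted p = 0.44 with an estimated correlation). Hsp90ab1 rose by 1.96 ± 0.11, Hspa8 by 1.89 ± 0.17, Hsp90aa1 by 1.54 ± 0.10 and Hspd1 by 1.11 ± 0.09.

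Genes controlled by the stress transcription factor ATF4 were split. Of 22, 11 were higher, 4 lower and 7 not called, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.065, but 0.010 with library totals and 0.026 without lactate replicate 3). Gdf15, a secreted stress cytokine, had the smallest p of all genes and went from 11.7 ± 1.58 to 2737 ± 147 CPM (SD, n = 3), a log2 fold change of 7.87 ± 0.15 (edgeR adjusted p = 8.3e-08). Fgf21, another secreted stress hormone, rose by 6.38 ± 0.42, the transcription factor Atf3 by 5.70 ± 0.25 and the phosphatase subunit Ppp1r15a by 3.80 ± 0.20. The list's median was 0.40 and its mean 1.33, and with library totals the median was −0.47, with 9 higher and 11 lower. The median was 0.61 with the length trend removed.

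**Figure D2:**
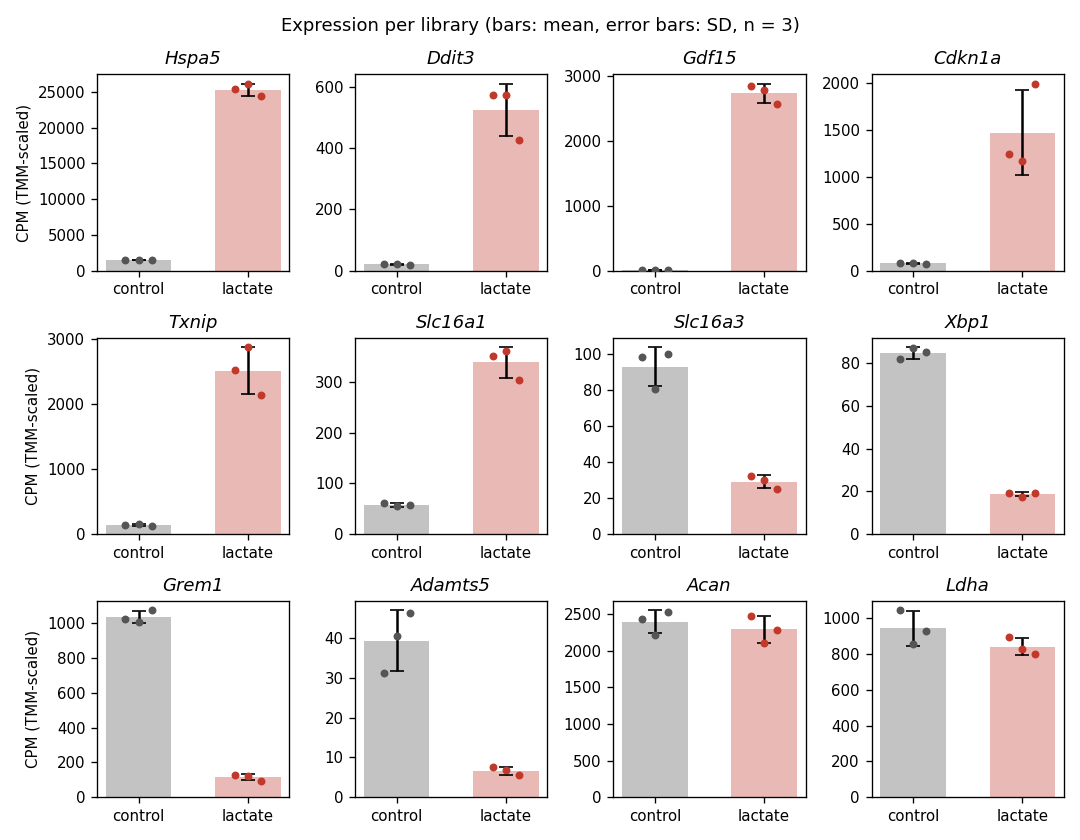
Expression of 12 genes in CPM scaled by TMM factors, for 3 control (grey) and 3 lactate (red) libraries. Bars are means, error bars are SD and points are libraries. Hspa5, Ddit3, Gdf15, Cdkn1a, Txnip and Slc16a1 lie higher and Slc16a3, Xbp1, Grem1 and Adamts5 lower in all 3 lactate libraries, while Acan (−0.06) and Ldha (−0.17) were not called with TMM factors and were lower with library totals (−0.92 and −1.03).

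Genes of p53 signalling and senescence rose. Of 18 p53 targets and senescence genes, 13 were higher, 3 lower and 2 not called, the same adjusted over the list alone (median 1.61, and 0.74 with 11 higher and 5 lower with library totals, and 1.84 with the length trend removed; camera adjusted p = 0.00059, and adjusted p = 0.42 with an estimated correlation). Cdkn1a, the cyclin-dependent kinase inhibitor p21, went from 77.4 ± 3.65 to 1470 ± 454 CPM (SD, n = 3), a log2 fold change of 4.25 ± 0.22 (edgeR adjusted p = 2.2e-06). Gadd45b rose by 5.02 ± 0.18, Mdm2, the ubiquitin ligase of p53, by 3.69 ± 0.13, Plk2 by 3.66 ± 0.12 and Phlda3 by 2.49 ± 0.09. Cdkn2b (−0.79), Fas (−1.16) and Igfbp5 (−3.17) fell, but Cdkn2b was at −0.39 and not called with the length trend removed. Of 21 mitosis genes, 11 were lower, 1 (Cdk1, 0.80) higher and 9 not called, and of 21 DNA replication genes, 10 were lower, 4 higher and 7 not called, in both cases the same adjusted over the list alone. With library totals 19 mitosis genes were lower and 0 higher (median −1.42, from −0.57), with Cdk1 at −0.04, and 18 DNA replication genes were lower and 0 higher (median −1.32, from −0.45). With the length trend removed the medians were −0.36 and −0.22. Neither list was called (camera adjusted p = 0.065 and 0.18), although mitosis passed with the replicate block (0.044) and without lactate replicate 3 (0.031) or control replicate 2 (0.034). Cenpf and Cenpe, of the kinetochore, fell by 2.08 ± 0.14 and 2.01 ± 0.14 (−1.30 and −1.35 with the length trend removed), the mitotic kinase Plk1 fell by 1.91 ± 0.16, the cyclin Ccna2 fell by 1.52 ± 0.12 and the replication licensing factor Cdc6 fell by 2.73 ± 0.17. Mki67, a marker of cycling cells, fell by 1.13 ± 0.20 (edgeR adjusted p = 0.0012), but with the length trend removed it was at −0.36 and not called (edgeR adjusted p = 0.085). The helicase subunits Mcm4 (−1.45 ± 0.12) and Mcm7 (−1.56 ± 0.15) fell as well.

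Apoptosis genes had 10 higher, 4 lower and 3 not called of 17, the same adjusted over the list alone, and were not called as a list (median 0.41, −0.46 with 3 higher and 10 lower with library totals, and 0.28 with the length trend removed; camera adjusted p = 0.17). The survival gene Bcl2l1 rose by 2.90 ± 0.10 and its antagonist Bcl2l11 by 1.86 ± 0.19, while Casp9, the initiator caspase, fell by 2.72 ± 0.19. Immediate early genes, which respond to signals within minutes to hours, rose in 15 of 21, with 1 lower and 5 not called (15 and 2 adjusted over the list alone; median 1.36, and 0.47 with 10 higher and 7 lower with library totals; camera adjusted p = 0.0016, and adjusted p = 0.55 with an estimated correlation). Ier5 rose by 3.95 ± 0.17, Dusp5 by 2.67 ± 0.13, Zfp36, which promotes the decay of cytokine mRNA, by 2.27 ± 0.15 and Ier3 by 2.15 ± 0.09.

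The transporters of lactate moved in opposite directions. Slc16a1, the monocarboxylate transporter MCT1, went from 57.2 ± 3.23 to 339 ± 30.8 CPM (SD, n = 3), a log2 fold change of 2.57 ± 0.11 (edgeR adjusted p = 1.3e-06), and its partner Bsg (basigin) rose by 1.80 ± 0.11. Slc16a3, the transporter MCT4 of glycolytic cells, fell by 1.68 ± 0.14 and the bicarbonate transporter Slc4a7 by 1.73 ± 0.15. The related transporter Slc16a7 was lower too, at −1.39 ± 0.21 (edgeR adjusted p = 0.0004). Of 11 genes of lactate and proton transport and sensing, 5 were higher and 6 lower, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.85). Its median was −0.52, with the camera direction up. The median was −1.37 with library totals (4 higher and 6 lower) and −0.01 with the length trend removed. The proton-sensing receptor Gpr4 had 0 control counts and 54 lactate counts, at least 36.2-fold higher against 3 counts over the control group, and with it at that bound the median stayed −0.52 and the mean was 0.40, against a mean of −0.08 without it. Of the lactate dehydrogenase subunits, Ldhb fell by 0.71 ± 0.21 (edgeR adjusted p = 0.015, lost at 0.061 without control replicate 1 and 0.059 without lactate replicate 1). Ldha differed by −0.17 ± 0.10 (edgeR adjusted p = 0.18) and was called with upper-quartile factors (−0.32) and library totals (−1.03). The receptor gene Hcar1 was not analysed here.

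Of 15 glycolysis genes, 10 were higher, 2 lower and 3 not called, the same adjusted over the list alone (median 0.58, and −0.29 with 4 higher and 8 lower with library totals). Camera gave an adjusted p of 0.052, and 0.036 with the length trend removed, 0.037 without control replicate 1 and 0.033 without lactate replicate 3. The glucose transporter Slc2a1 rose by 1.89 ± 0.09, Pfkfb3, which makes the activator of phosphofructokinase, by 2.58 ± 0.16 and Pgam1 by 1.04 ± 0.09, while Pfkl fell by 1.81 ± 0.12. Pgam1 was at 0.17 and not called with library totals. In the TCA cycle 16 of 20 genes were higher, 2 (Idh3a, −0.81, and Idh2, −0.88) lower and 2 not called, the same adjusted over the list alone (median 0.53; camera adjusted p = 0.0022, and adjusted p = 0.42 with an estimated correlation). With library totals its median was −0.33, with 3 higher and 11 lower, and the list was not called (camera adjusted p = 0.42). Sdhd and Pdhb rose by 1.24 ± 0.12 and 1.22 ± 0.12, and Mdh2 by 0.89 ± 0.08 (0.02, not called, with library totals).

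Nuclear genes of oxidative phosphorylation rose in 22 of 25, with 0 lower, the same adjusted over the list alone (median 1.04; camera adjusted p = 2e-06, and adjusted p = 0.45 with an estimated correlation). The median was 0.67 with the length trend removed, and library totals gave 0.18 with 7 genes higher and 4 lower. Cox6c rose by 1.67 ± 0.10, Cox4i1 by 1.63 ± 0.11, Cox5a by 1.42 ± 0.10 and Ndufb5 by 1.40 ± 0.10, and with the length trend removed they were at 0.71, 1.09, 0.68 and 1.19. The mitochondrially encoded genes did not rise as a list, and were not tested against the nuclear genes. Of 13, 3 were higher, 7 lower and 3 not called, the same adjusted over the list alone (median −0.66, −1.52 with 1 higher and 11 lower with library totals, and −1.16 with the length trend removed; camera adjusted p = 0.40, and 0.034 with the length trend removed). Mt-co1 rose by 1.36 ± 0.14, while Mt-nd4l fell by 1.75 ± 0.18, Mt-nd4 by 1.38 ± 0.16 and Mt-co2 by 1.12 ± 0.13. With the length trend removed Mt-nd4l was at −3.02, Mt-co2 at −1.74 and Mt-nd4 at −1.45. That removal used relative lengths from counts and FPKM (0.14 for Mt-nd4l), not measured lengths of these RNAs. The mitochondrially encoded list passed only in this setting. Hypoxia response genes had 11 higher, 5 lower and 3 not called of 19, the same adjusted over the list alone (median 0.62, and −0.24 with 7 higher and 7 lower with library totals; camera adjusted p = 0.14). Bhlhe40 rose by 3.72 ± 0.26, the vasodilator Adm by 2.51 ± 0.16, Kdm3a by 1.70 ± 0.11 and Ero1a by 1.51 ± 0.10. The genes called lower were Egln1 (−1.67), Bnip3l (−1.21), Stc2 (−0.93), Bnip3 (−0.78) and Pdk1.

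**Figure D3:**
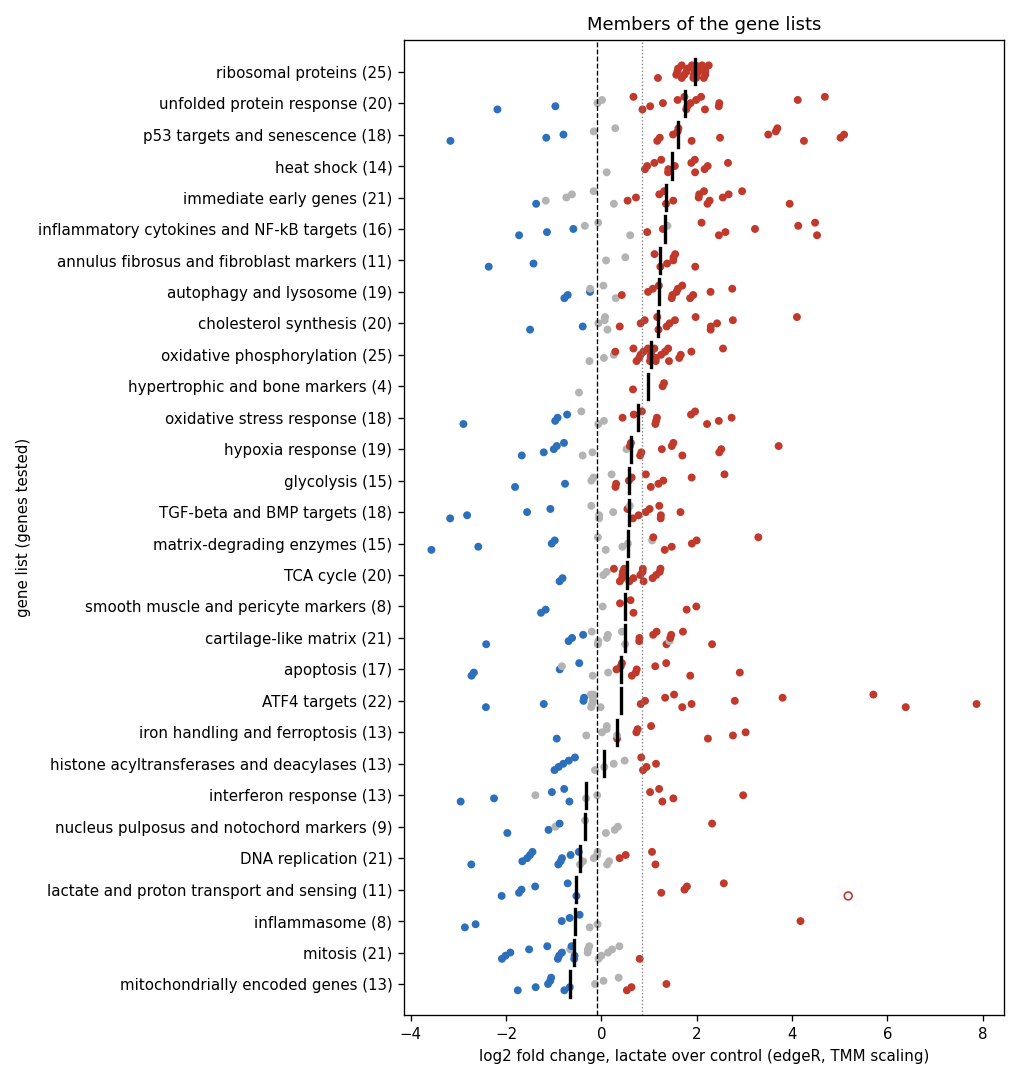
Log2 fold change (lactate over control, TMM scaling) of each tested member of 30 gene lists, ordered by median (black bars). Red points were called higher, blue points lower and grey points not called by edgeR, and the open point, Gpr4, stands at its lower bound. The dashed line is the median of all genes (−0.10), and the dotted line marks where library totals would put 0. Ribosomal proteins (median 1.96) lie furthest to the right, and the medians of the TCA cycle and 11 other lists lie right of the dashed line and turn negative with library totals.

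Genes of the cartilage-like matrix of the disc were mixed. Of 21, 9 were higher, 4 lower and 8 not called, the same adjusted over the list alone (median 0.50, and −0.36 with 4 higher and 7 lower with library totals; camera adjusted p = 0.14, and 0.029 with the length trend removed). Acan, the proteoglycan aggrecan, was at 2393 ± 159 CPM in control and 2290 ± 183 in lactate libraries (SD, n = 3; −0.06 ± 0.10, edgeR adjusted p = 0.59). It was called lower with library totals (−0.92) and higher with the length trend removed (0.53). Bgn rose by 1.71 ± 0.17, Comp by 1.46 ± 0.18, Col11a1 by 1.16 ± 0.15 (1.83 with the length trend removed) and Col6a1 by 0.80 ± 0.11, which was −0.07 and not called with library totals. Sox9, the master regulator of cartilage genes, rose by 1.45 ± 0.28 (edgeR adjusted p = 0.0016, and 0.067 with library totals). Col2a1 had only 39 control and 55 lactate counts and was not called (1.43 ± 0.83, edgeR adjusted p = 0.16).

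Of 9 nucleus pulposus and notochord markers tested, 1 was higher, 3 lower and 5 not called, the same adjusted over the list alone (median −0.34, and −1.21 with 1 higher and 6 lower with library totals; camera adjusted p = 0.67). Cd24 rose by 2.32 ± 0.13, while Foxa2, Pax1 and Cdh2 fell by 1.97 ± 0.36, 0.88 ± 0.18 and 1.11 ± 0.25, the last at −0.69 with the length trend removed. Tbxt (brachyury) had 12 control counts and 0 lactate counts and Krt19 had 9 and 0, both under the filter. Annulus fibrosus and fibroblast markers had 7 higher, 2 lower and 2 not called of 11, the same adjusted over the list alone (median 1.24, and 0.37 with 7 higher and 3 lower with library totals; camera adjusted p = 0.065, but 0.0082 with library totals and 0.033 without lactate replicate 3). Col1a1 rose by 1.97 ± 0.16, to 124372 ± 22630 from 31785 ± 2955 CPM (SD, n = 3), and Thy1 by 1.24 ± 0.10. The tendon transcription factor Mkx fell by 2.36 ± 0.17 and Pdgfra by 1.42 ± 0.11 (−0.83 with the length trend removed).

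Among hypertrophic and bone markers 3 of 4 were higher and 1 not called, the same adjusted over the list alone (median 0.97, 0.11 with 1 higher and 1 lower with library totals, and 1.22 with the length trend removed; camera adjusted p = 0.29). Spp1 (osteopontin) rose by 1.28 ± 0.14, Runx2 by 0.66 ± 0.18 and Alpl by 1.31 ± 0.38. Runx2 rose further with the length trend removed. Runx2 (−0.21) and Alpl (0.43) were not called with library totals, and Alpl lost its call without control replicate 1 (edgeR adjusted p = 0.054) and without lactate replicate 1 (0.053). Smooth muscle and pericyte markers had 5 higher, 2 lower and 1 not called of 8, the same adjusted over the list alone (median 0.50, and −0.36 with 2 higher and 5 lower with library totals; camera adjusted p = 0.28), with Des at 1.99 ± 0.14 and Mcam at 1.79 ± 0.17 against Pdgfrb at −1.27 ± 0.12 and Myh11 at −1.17 ± 0.16 (−0.84 and −0.56 with the length trend removed). Of the macrophage markers tested, Cd14 fell by 1.72 ± 0.19 and Cd68 was at 1.48 ± 0.40, with 76 control and 109 lactate counts (not called with library totals). Of the endothelial markers tested, Flt1 (0.15) and Vwf (0.39), 0 were called, though Flt1 was called lower with library totals (−0.72) and higher with the length trend removed (0.78), where Vwf was at 1.09.

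Matrix-degrading enzymes also went both ways. Of 15, 6 were higher, 4 lower and 5 not called, the same adjusted over the list alone (median 0.56, −0.31 with 4 higher and 6 lower with library totals, and 0.98 with the length trend removed; camera adjusted p = 0.29). Plau (urokinase) rose by 3.29 ± 0.26 and the serine protease Htra1 by 1.90 ± 0.11, while the aggrecanase Adamts5 fell by 2.58 ± 0.19 and Adamts9 by 3.56 ± 0.29. Mmp3 was at 1.09 ± 0.34 (edgeR adjusted p = 0.019), and its call was lost without control replicate 1 (0.079), control replicate 2 (0.057) or lactate replicate 3 (0.059), and with library totals (0.57). Mmp13 (0.56 ± 0.24, edgeR adjusted p = 0.073) passed without control replicate 3 (0.035) or lactate replicate 3 (0.023), and Adamts4 was not called (0.44 ± 0.29, edgeR adjusted p = 0.21). With the length trend removed Mmp13 (0.77) and Adamts4 (0.98) were called. TGF-beta and BMP targets had 9 higher, 4 lower and 5 not called of 18, the same adjusted over the list alone (median 0.57, mean 0.07, and median −0.29 with 4 higher and 8 lower with library totals; camera adjusted p = 0.28). Grem1, an antagonist of BMPs, fell from 1036 ± 35.3 to 115 ± 18.7 CPM (SD, n = 3; −3.17 ± 0.13), Bmp4 by 2.82 ± 0.13 and Id2 by 1.56 ± 0.12, and Tgfb1 rose by 1.24 ± 0.09.

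Of 16 inflammatory cytokines and NF-kB targets, 9 were higher, 3 lower and 4 not called, the same adjusted over the list alone (median 1.34, and 0.47 with 7 higher and 5 lower with library totals; camera adjusted p = 0.065, 0.0010 with library totals and 0.048 without lactate replicate 3). Nfkbia, the inhibitor of NF-kB, rose by 4.48 ± 0.20, the chemokine Cxcl1 by 2.60 ± 0.17 and Nfkbiz by 2.46 ± 0.20, while Nfkb1 fell by 1.73 ± 0.13. Ptgs2 (cyclooxygenase 2) fell by 1.14 ± 0.20 (−0.72 with the length trend removed). Il6 had 10 control and 6 lactate counts, under the filter, and Il1b was not analysed here. Of 8 inflammasome genes 1 was higher, 5 lower and 2 not called, the same adjusted over the list alone (median −0.56, and −1.41 with 1 higher and 6 lower with library totals; camera adjusted p = 0.33). The riser was Txnip, a thioredoxin-binding protein that also restrains glucose uptake, at 4.18 ± 0.16 (139 ± 19.1 to 2514 ± 364 CPM; SD, n = 3). Nlrp1a, Gsdmd and Nek7 fell by 2.86 ± 0.49, 0.46 ± 0.12 and 0.67 ± 0.18. Interferon response genes had 5 higher, 5 lower and 3 not called of 13 (5 and 6 adjusted over the list alone; median −0.32, and −1.17 with 1 higher and 8 lower with library totals; camera adjusted p = 0.90). Irf1 rose by 2.97 ± 0.16 and Ifi27 by 1.28 ± 0.20 (0.41, not called, with library totals, and 0.83 with the length trend removed), while Ifit2 fell by 2.95 ± 0.17.

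Oxidative stress genes had 11 higher, 4 lower and 3 not called of 18, the same adjusted over the list alone (median 0.76, and −0.10 with 5 higher and 8 lower with library totals; camera adjusted p = 0.065, 0.030 with library totals and 0.037 without control replicate 1). Heme oxygenase Hmox1 rose by 2.22 ± 0.10 and the glutathione peroxidases Gpx1 and Gpx4 by 2.73 ± 0.17 and 1.96 ± 0.11, and Keap1, the repressor of NRF2, fell by 2.89 ± 0.15. Of 13 iron handling and ferroptosis genes 7 were higher, 1 lower and 5 not called, the same adjusted over the list alone (median 0.33, −0.51 with 3 higher and 6 lower with library totals, and 0.63 with the length trend removed). Camera gave an adjusted p of 0.052, and 0.014 with the length trend removed, and the list passed without control replicate 1 (0.037), lactate replicate 2 (0.043) or lactate replicate 3 (0.045). The ferritin chains Ftl1 and Fth1 rose by 3.03 ± 0.13 and 2.23 ± 0.13 and the polyamine enzyme Sat1 by 2.76 ± 0.14. Steap3 was at 0.76 ± 0.12, and at −0.09 and not called with library totals.

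Cholesterol synthesis genes rose, 14 of 20 with 2 lower and 4 not called, the same adjusted over the list alone (median 1.18, 0.32 with 10 higher and 7 lower with library totals, and 1.53 with the length trend removed; camera adjusted p = 0.00092, and adjusted p = 0.55 with an estimated correlation). Insig1, a brake on sterol synthesis, rose by 4.10 ± 0.23, the cholesterol carrier Stard4 by 2.76 ± 0.13, Cyp51 by 2.43 ± 0.13 and Msmo1 by 2.30 ± 0.13. Autophagy and lysosome genes rose in 13 of 19, with 3 lower and 3 not called, the same adjusted over the list alone (median 1.21, and 0.35 with 10 higher and 7 lower with library totals; camera adjusted p = 0.0016, and adjusted p = 0.42 with an estimated correlation). Gabarapl1 rose by 2.74 ± 0.12, the lysosomal proteases Ctsd and Ctsb by 2.29 ± 0.11 and 1.86 ± 0.10, and Atg12 by 1.93 ± 0.11. All 25 ribosomal protein genes tested rose, also with library totals and adjusted over the list alone (median 1.96, 1.09 with library totals and 1.30 with the length trend removed; camera adjusted p = 1.1e-10, and adjusted p = 0.55 with an estimated correlation). Rps2 rose by 2.25 ± 0.09, Rps16 by 1.99 ± 0.10, Rpl14 by 1.74 ± 0.09 and Rpl19 by 1.68 ± 0.09, and with the length trend removed they were at 1.90, 1.46, 1.17 and 1.09. Histone acyltransferases and deacylases had 4 higher, 5 lower and 4 not called of 13, the same adjusted over the list alone (median 0.06, −0.10 with upper-quartile factors, −0.80 with 0 higher and 7 lower with library totals, and 0.21 with the length trend removed; camera adjusted p = 0.85). Crebbp, Kat7 and Sirt2 were at 1.15 ± 0.18, 0.95 ± 0.13 and 0.84 ± 0.13, none called with library totals (0.30, 0.10 and −0.03), with Crebbp at 1.94 with the length trend removed, and Kat5 fell by 0.80 ± 0.14. Across the 30 lists camera called 9, all of them higher, and 0 with an estimated correlation, where the smallest adjusted p was 0.42. With library totals it called 12, which held 8 of the 9, without the TCA cycle, and 4 more. For DESeq2, camera was run on its test statistics, without the low-count filter, in place of log2 CPM. That called 8 more than the 9: glycolysis, hypoxia, mitosis, iron handling, ATF4 targets, oxidative stress, inflammatory cytokines and annulus fibrosus markers. Of these, limma-voom called 5 (glycolysis, mitosis, iron handling, oxidative stress and annulus fibrosus markers), RLE factors 2 (glycolysis and iron handling), and the test without a low-count filter 7, without hypoxia.

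The largest rises by the rule were led by genes near 0 in control. Trarg1 and Stmn4 had 0 control counts and were at least 372-fold and 226-fold higher, against 3 counts over the control group. Phlda2 had 2 control counts, with a ratio of 194 (95% counting interval 52.9 to 1612). Besides Gdf15, Fgf21 and Atf3, the G protein Rasd2 rose by 7.71 ± 0.42, Rem2 by 5.81 ± 0.18 and the keratin Krt17 by 5.63 ± 0.52. Control counts over the group were only 9 for Rasd2, 12 for Fgf21 and 35 for Krt17. Among the largest falls, Dcun1d2 and Hdhd3 had 3 lactate counts each, with ratios of control over lactate of 129 (95% counting interval 43.8 to 625) and 56.9 (19.3 to 277). Smad9, a transducer of BMP signals, fell by 5.71 ± 0.83, and Bbs12, a chaperonin-like protein of the cilium, fell by 5.32 ± 0.60. Nudt13 (−5.51 ± 0.78), Homez (−5.21 ± 0.67) and Lacc1 (−5.10 ± 0.60) fell too. Lactate counts over the group were only 7 for Smad9, 7 for Bbs12, 4 for Nudt13, 4 for Homez and 6 for Lacc1. The sizes of these falls are therefore uncertain. Disp2 (−4.83 ± 0.37), Jrk (−4.73 ± 0.40) and Brms1l (−4.72 ± 0.38) fell as well. Each gene named here had an edgeR adjusted p of 0.00034 or less. Intervals and bounds cover counting error only.

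The authors' deposited table selects 6359 of 17273 genes, 2674 up and 3685 down. In the authors' deposited table these were the genes with an unadjusted p under 0.05 and a change of at least 2-fold, and 262 of them had an adjusted p of 0.05 or more. Of the 5765 selected genes that passed the count filter, 5600 were called with edgeR in the same direction. The log2 fold changes of the authors' deposited table lay 0.04 lower in the median (−0.04). The authors' deposited table gives 7.83 for Gdf15, 4.08 for Hspa5, 2.53 for Slc16a1 and −0.10 for Acan.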

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

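Removal of the length trend and leaving out the 32 genes with 0 and over 1000 counts were chosen after seeing the data, and the other alternatives before. The count of changed genes (9079) stayed within 8026 to 10214 over all alternatives at an adjusted p of 0.05 and was 7294 at 0.01, and the count at 2-fold (5588) stayed within 5040 to 7228. Leaving out a library gave 8026 to 9407 and 5294 to 5727. With library totals 6482 of 10214 calls were shared with TMM in the same direction. DESeq2 gave no adjusted p for 1053 genes. The number of gene lists called (9) was less stable: 16 without a low-count filter, 17 with DESeq2, 14 with limma-voom, 24 with fry, which asks another question, and 0 with an estimated correlation, where the 9 to 24 called otherwise held all of the 9 except the TCA cycle with library totals. Leaving out a library gave 9 to 15, the 15 without lactate replicate 3; the cause was not tested. The mean correlation between groups moved from 0.863 to 0.167, and that within groups from 0.968 to 0.684, on the 500 most variable genes, which are chosen to differ. The replicate block gave 8814 genes, 5481 at 2-fold and 10 lists. Deviations of same-numbered libraries correlated at 0.008, 0.038 and 0.084, and not every library correlated best with its own number. These values give no sign that the numbers pair the libraries, but 3 libraries per group are too few to exclude it.

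With library totals, log2(FPKM + 1) and log2(FPKM + 0.1), 4 genes called higher with TMM turned negative without a call: Col6a1 (−0.067, −0.075 and −0.075), Steap3 (−0.093, −0.10 and −0.11), Sirt2 (−0.031, −0.048 and −0.049) and Runx2 (−0.21, −0.20 and −0.22). The common shift of all genes under these scalings accounts for the sign. Acan turned to 0.53 with the length trend removed. Library totals ended 9 further calls among the named genes. Low counts, at most 55 per group, limit what can be said of Tbxt, Krt19, Il6 and Col2a1.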

Other observations

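The tests of library depth, of the most abundant genes and of read assignment, the trend on level, the interval of the difference between 2 lists, and the lists of clock, amino acid and MondoA genes, were chosen after their results had been seen; the other lists and tests here were written before theirs. Genes of secretory pathway transport had 16 higher and 2 lower of 21 (median 0.74, and −0.12 with 5 higher and 7 lower with library totals; camera adjusted p = 0.0026, and adjusted p = 0.38 with an estimated correlation), with Tmed10 at 1.66, Ssr2 at 1.53 and Kdelr1 at 1.31. The proteasome had 13 higher and 2 lower of 22 (median 0.53, −0.32 with 4 higher and 11 lower with library totals, and 0.31 with the length trend removed; camera adjusted p = 0.0086, lost at 0.15 with the length trend removed, and adjusted p = 0.52 with an estimated correlation). Cilium assembly genes fell, 18 of 24 with 1 higher (median −0.87, −1.73 with 0 higher and 24 lower with library totals, and −0.62 with the length trend removed; camera adjusted p = 0.0031, and adjusted p = 0.38 with an estimated correlation), with Ttc8 at −3.51 and Ift81 at −2.60. DNA repair genes fell in 16 of 24, with 1 (Msh6, 0.92, and 0.07 and not called with library totals) higher (median −0.72, −1.58 with 0 higher and 21 lower with library totals, and −0.42 with the length trend removed; camera adjusted p = 0.0086, lost at 0.11 with the length trend removed, and adjusted p = 0.38 with an estimated correlation), with Brca1 at −3.31. Aminoacyl-tRNA synthetases (5 higher and 7 lower of 14, and 2 and 12 with library totals; camera adjusted p = 0.81) and YAP and SRF targets (6 higher and 7 lower of 16, and 0 and 13 with library totals; camera adjusted p = 0.90) were not called. Their medians were −1.07 and −0.94 with library totals, and 0.05 and 0.18 with the length trend removed.

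Genes of the circadian clock were gathered because some had been seen to move, so their counts are no test. Of 13 clock output and repressor genes 9 were higher and 2 lower, and 9 and 4 with library totals. Nr1d1, a repressor of the clock, rose by 5.25, Ciart by 4.51, Per1 by 3.91 and Dbp by 2.55, while Per3 (−1.33, and −0.88 with the length trend removed) fell. Of 4 clock activator genes Rora rose by 2.31, Clock (−0.98) and Npas2 (−1.36) fell and Arntl was at −0.24, not called. These were at 1.45, −1.83, −2.21 and −1.13 with library totals, where Arntl was called, and at 2.35, −0.52, −0.96 and 0.03 with the length trend removed. Txnip and Arrdc4, targets of the nutrient-sensing factor MondoA, rose by 4.18 and 2.59.

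Short transcripts were higher and long transcripts lower in lactate libraries, with a Spearman correlation of −0.24 across 13747 genes, which are not independent replicates. Single libraries against the others of their group gave −0.14 to 0.12. The correlation was −0.240 after thinning every library to 30291357 counts, which decides little, since the totals of the groups overlapped. Thinning every library to a median of 119 counts per gene, which kept 30.5 to 34.7% of the control counts, left the correlation at −0.246. Thinning scales all genes of a library by a common factor, so fold changes could shift only in genes with few counts. This decides little on a difference in the depth of the typical gene. The correlation was −0.241 without 137 abundant genes. This decides nothing on the larger share of a few abundant genes, since so few genes could not move a rank correlation over all. A loss of long RNA in lactate libraries stays open: among the most abundant genes, long ones had a median log2 fold change 0.53 lower than those of middle length (−0.534, 95% bootstrap interval −0.661 to −0.428). This may be fragmentation or size selection, or a cellular response to lactate that spares short transcripts, which was not tested. Fold changes followed level besides length: the Spearman correlation of log2 fold change with mean log2 CPM was 0.32, and long genes were at 0.10 among the most abundant genes and at −0.52 over all levels. Ribosomal protein genes had a median log2 CPM of 9.28, those of the unfolded protein response 7.47 and of oxidative phosphorylation 6.17, against 3.65 for all genes, 3.32 for cilium assembly and 4.05 for DNA repair. Of the proteasome genes 21 of 22 were among the 2750 genes with the highest mean log2 CPM. Those 2750 had a median log2 fold change of 0.55, near the 0.53 of the proteasome list. How far the level trend makes these lists rise or fall was not tested.

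In 32 genes 1 library had 0 counts and another over 1000, and in 30 of them both a 0 and over 100 counts occurred within one group. This may come from reads assigned to another overlapping or near-identical feature, differently in each library, which stays open, since overlaps and near-identical genes were not looked for. Myh9 had 20121, 66521 and 0 control counts and 0 in all lactate libraries, and the authors' deposited table gives it a log2 fold change of −17.36. Of the 23 such genes that were tested, edgeR called 2, AABR07000398.1 and Rattus_newGene_14525. Myh9 and these 2 were picked out after their values were seen.

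Genes of the unfolded protein response rose as a list (camera adjusted p = 5.2e-05, and adjusted p = 0.45 with an estimated correlation). Genes of amino acid synthesis and import, which ATF4 also controls, did not rise as a list. The amino acid list also held the ATF4 targets Trib3 and Chac1, which are not genes of synthesis or import. This list had 4 higher, 2 lower and 8 not called of 14 (median −0.18, −1.05 with 1 higher and 10 lower with library totals, and 0.04 with the length trend removed). Slc3a2 (1.52), Mthfd2 (0.92), Slc7a5 (0.83) and Slc6a9 (0.56) rose, Slc7a11 (−2.42) and Asns (−0.38) fell, and Trib3 (−0.19) and Chac1 (−0.17) were not called. With library totals only Slc3a2 (0.66) of the risers was higher, and with the length trend removed Asns (−0.22) was not called and Slc6a9 was at 0.86. The medians of the unfolded protein response and amino acid lists differed by 1.94. A single library is argued against as the cause, since the smallest difference with 1 library left out was 1.82. With the length trend removed the difference was 1.79 (95% bootstrap interval over genes 0.84 to 2.34). For these genes the trend as the whole cause is argued against, while the interval is too wide to exclude a large share. The amino acid list was chosen after its result had been seen. The interval does not allow for that choice, so it says nothing on genes beyond these lists. A different response of these lists to lactate was not tested.

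With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 9079 genes, 5588 at 2-fold, and the highest other split 0 for both (1 split of 10 as large). For gene lists the real split called 9 and the highest other 14, and 5 of 10 splits called as many. Each other split mixed libraries of both groups, so part of the group difference stayed in it and the rest added to the spread. Counts from these splits are therefore no chance level.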
